A study of Sus scrofa with 12 samples.

How the data were processed

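Testis tissue of 12-month-old adult male pigs was sequenced in 2 ways, as ribosomal RNA-depleted total RNA with paired-end reads and as small RNA from a TruSeq small RNA kit with single-end reads. The groups analysed were the breeds Duroc and Large white, with 3 libraries per breed in each assay and 12 libraries in all. The series' design also names the Diannan small-ear breed, which was not analysed here. The labels do not say whether an RNA library and a small RNA library with the same number came from one animal, nor that each library came from a different animal. The p-values therefore measure the spread between libraries, which may in part be technical.

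Per the submitters' processing notes, the tools were STAR 2.7.10a, Salmon 1.9.0 and Bowtie 1.3.1, with the build susScr11. Which tool made which values, and the transcript annotation, are not given in the sources used here. The deposited RNA files listed 63022 Ensembl pig transcripts with their length, effective length, TPM (length-scaled relative abundance) and an estimated count of reads, per the file headers, which are those of Salmon's output. TPM as the authors deposited it divides by effective length. A transcript of 144 bases with effective lengths between 31.4 and 34.2 bases held 19.4% to 24.7% of all TPM but 0.499% to 0.668% of the estimated reads, so that the level of every other transcript in TPM carries that share. The deposited small RNA files gave whole read counts per mature miRNA and precursor. They also gave RPM, the reads scaled by the authors to the sum of those counts. A mature miRNA with several precursors stood several times in these files over the same reads. The 845 entries held 765 distinct names, 67 of which stood more than once, and the entry with the most reads was kept for each name. Entries named after a chromosome and a serial number are loci without a miRNA name and are called unnamed loci.

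No table used here pairs the Ensembl transcripts with genes. Transcripts were therefore tested singly, without gene names, long non-coding classes or gene sums, and 22 gene lists fixed before the data were examined were not used. The fixed naming rule took 10 genes with a symbol in each direction. With no symbols, the 2 transcripts of smallest p in each direction are named by identifier. For miRNAs the rule took the 3 of smallest p in each direction where none passed, the 5 most abundant, and the most abundant member of each list. Others that are named were chosen after their values were seen.

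The test planned for files of TPM and RPM was limma on log2 values. As the files also held reads, transcripts and miRNAs were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test with TMM scaling and breed as the only term, on estimated reads rounded to whole numbers and on miRNA read counts. Transcripts had to reach a TPM of 1, and miRNAs an RPM of 1, in at least 3 of the 6 libraries. All p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Log2 fold changes are Duroc minus Large white, and their standard errors (SE) are the fold change over the square root of the test's F, which is an approximation. miRNA levels are TMM-normalised RPM. In Duroc library 1 the scale factor was 0.464, so that the level of an abundant miRNA can there exceed the total to which RPM is scaled. Shares of reads are therefore given for the 5 most abundant miRNAs.

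The 11 miRNA lists, for the DLK1-DIO3 imprinted cluster, the miR-17-92 clusters, smooth muscle and stroma, an X-linked region, spermatogonia, Sertoli and Leydig cells, blood cells, striated muscle, the miR-200, let-7 and miR-34/449 families, were fixed before the data were examined. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01. Estimated correlations and fry were run beside it. The lists share members, for example miR-21-5p in stroma and spermatogonia and miR-363 in the miR-17-92 and X-linked lists. The DLK1-DIO3 list had been given miR-542 by mistake, which lies on the X chromosome, and it was also tested without it. Places of precursors come from a RefSeq table of the pig assembly Sscrofa11.1, the assembly that susScr11 denotes. It placed 199 of the 230 precursors of the tested named miRNAs. Strand was not given there. Names with the same or near-identical sequence shared reads, such as miR-129a-5p and miR-129b, miR-199a-3p and miR-199b-3p, and miR-218, miR-218-5p and miR-218b, and are not separate measurements.

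The floor for an absent transcript was 3 reads per library, which covers counting error only. With counts simulated from the means and dispersions of these libraries, 200 of 24225 transcripts were changed. edgeR recovered 0 of 67 changed 2-fold, 2 of 67 changed 4-fold and 16 of 66 changed 8-fold, with 1 false call. DESeq2 1.42.0 recovered 3, 41 and 57 of these with 87 false calls. Among 421 simulated miRNAs, edgeR recovered 5 of 20 changed 2-fold, 19 of 20 changed 4-fold and 19 of 20 changed 8-fold with 1 false call. camera called an 11-member list shifted 2-fold in 20 of 20 draws, and 0 of 20 when unshifted; the miRNAs of these draws varied independently. Alternatives covered limma on log2(TPM + 1) or log2(RPM + 1) and other pseudocounts, filters, scalings, DESeq2, the replicate number as a block, each library left out, and Duroc library 2 alone against Large white. In the last, Duroc has no spread of its own and the Large white libraries alone supply it, so its p-values are given as description. It and DESeq2 on transcripts were added after the data had been examined, while limma with a pseudocount of 1 was the test first planned.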

Results

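The series measured RNA and small RNA of adult pig testis to relate long non-coding RNA, miRNA and mRNA levels to testis function. The comparison analysed here was between Duroc and Large white, both commercial breeds. The RNA libraries held 24111576, 19847640 and 17922861 estimated reads in Duroc libraries 1 to 3 and 25520578, 22985006 and 20554627 in Large white libraries 1 to 3. The small RNA libraries held 13209412, 3473206 and 9161673 reads in Duroc and 1481386, 2483001 and 1600804 in Large white, with reads listed under several precursors counted each time. A floor of 3 reads there corresponds to between 0.227 and 2.03 RPM.

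Few single transcripts passed the adjusted threshold between the breeds, and those named here differed by large factors. In the simulation edgeR recovered 0 of 67 transcripts changed 2-fold and 16 of 66 changed 8-fold. Smaller differences could thus have been missed, and the few calls do not show that few transcripts differ. ENSSSCT00000012334.4 had 423 ± 187 TPM in Duroc against 11.3 ± 1.79 in Large white (SD, n = 3 each). ENSSSCT00000084379.1 had 118 ± 5.97 TPM in Duroc against 10.9 ± 1.61 in Large white. ENSSSCT00000085589.1 was nearly absent from Duroc, at 0.747 ± 0.092 TPM against 74.6 ± 7.22 in Large white. ENSSSCT00000083579.1 had no read assigned to it in any Duroc library against 81.5 ± 10.7 TPM in Large white. That is at least 1023-fold lower in Duroc by the floor of 3 reads per library. Reads were estimated per transcript and no gene sums were made. Absence can therefore not be told from assignment of reads to another transcript of the same gene.

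By edgeR's quasi-likelihood test, 9 of 24227 transcripts passed the adjusted threshold, of which 4 were higher in Duroc and 5 in Large white. Of the 9, 3 had no read assigned in the Duroc libraries. The log2 fold change was 5.12 (SE 0.38, adjusted p = 0.0145) for ENSSSCT00000012334.4 and 3.37 (SE 0.27, adjusted p = 0.0145) for ENSSSCT00000084379.1. It was -6.70 (SE 0.37, adjusted p = 0.00656) for ENSSSCT00000085589.1, and the adjusted p of ENSSSCT00000083579.1 was 0.0125. Before adjustment, 3351 transcripts lay under 0.05. The values of the breeds did not overlap in 4376 transcripts, or 18.1%, where chance gives 10%. Quantile normalisation with limma called 9 transcripts higher and 18 lower in Duroc. The count was 8373 without Duroc library 2, of which 4964 were higher and 3409 lower in Duroc. It was 4 without Duroc library 3, all lower in Duroc, and 0 without any 1 of the Large white libraries. Without Duroc library 3, edgeR's adjusted p was 0.0783 for ENSSSCT00000012334.4 and 0.115 for ENSSSCT00000084379.1. Without the filter that of ENSSSCT00000084379.1 was 0.0615. The smallest adjusted p was 0.114, 0.116 and 0.0859 without Large white libraries 1, 2 and 3, and the log2 fold change of ENSSSCT00000085589.1 was then between -6.78 and -6.66. The median log2 fold change of all transcripts was 0.07 with TMM and 0.19 with total scaling. DESeq2 called 428 transcripts, 305 higher and 123 lower in Duroc, and called 87 unchanged ones in the simulation.

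Duroc libraries 1 and 3 stood apart from the other 4 in both assays. Between 2 Large white libraries, 206 to 269 transcripts differed by more than 4-fold, with 1 added to each TPM or normalised RPM. Against a Large white library, 2276 to 2492 did so in Duroc library 1, 1032 to 1089 in Duroc library 3 and 327 to 377 in Duroc library 2. Among miRNAs, 5 to 7 differed by more than 4-fold between 2 Large white libraries, 23 to 46 for Duroc library 1, 12 to 24 for Duroc library 3 and 5 to 7 for Duroc library 2. The first component held 67.7% of the variance of transcripts and 50.8% of that of miRNAs, and on the second component the Large white libraries lay between Duroc libraries in RNA and overlapped with them in small RNA.

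**Figure D1:**
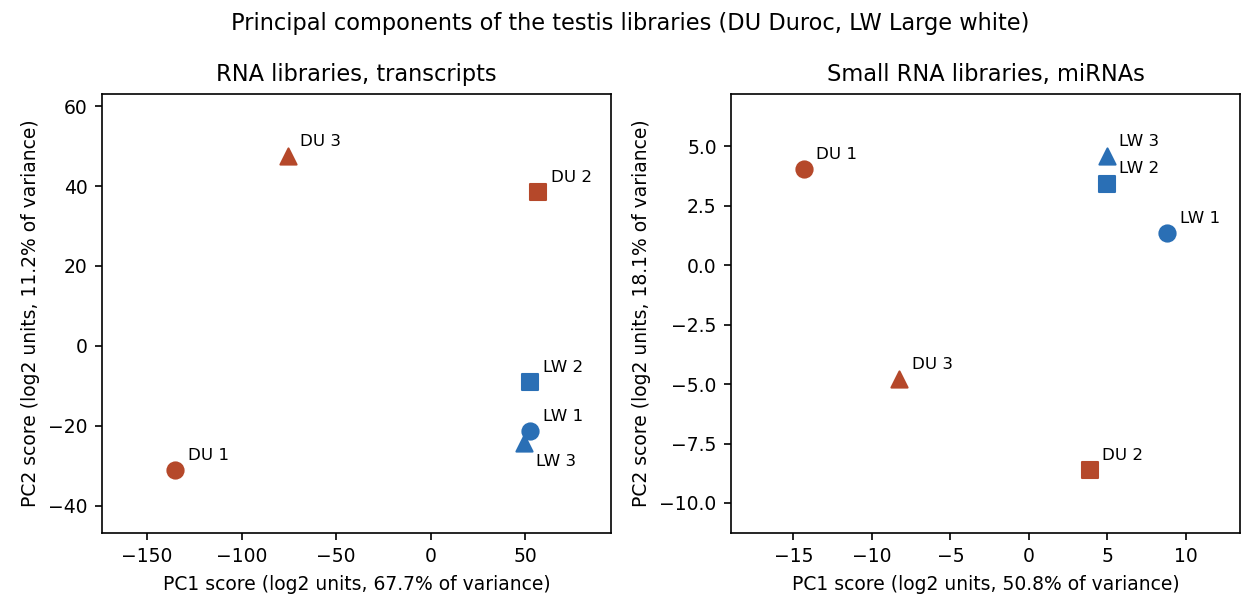
Scores on the first 2 principal components (log2 units) of the 6 RNA libraries (left, log2(TPM + 1) of 24227 transcripts) and the 6 small RNA libraries (right, log2(normalised RPM + 1) of 421 miRNAs), with breed as colour and library number as symbol. In both panels Duroc libraries 1 and 3 lie to the left, and Duroc library 2 lies near the Large white libraries on the first axis, which holds 67.7% and 50.8% of the variance.

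A single miRNA, miR-143-3p, had the highest mean share of reads in testis of both breeds, although miR-148a-3p exceeded it in Large white library 1, with 21.7% against 18.9%. It lies on chromosome 2 at 150578738 to 150578817 of Sscrofa11.1, within the span of IL17B, and is known as a miRNA of smooth muscle. Its share was 37.5 ± 13.1% in Duroc and 23.4 ± 5.42% in Large white (SD, n = 3 each), and the 51.5% of Duroc library 1 was the highest. miR-148a-3p followed with 18.9 ± 3.98% and 19.0 ± 2.44%, and miR-99a-5p with 5.57 ± 0.33% and 5.24 ± 1.04%. miR-26a held 3.69% to 4.19% in the Duroc libraries and 4.77% to 5.14% in the Large white libraries, and miR-21-5p 4.03 ± 0.42% and 4.57 ± 1.09%. These 5 took 78.9%, 59.5% and 71.7% of the reads in Duroc libraries 1 to 3 and 55.4%, 56.1% and 60.4% in the Large white libraries. None of the 5 passed edgeR's test. With its TMM scaling the log2 fold change was 0.47 for miR-26a and 0.63 for miR-21-5p, so their direction was opposite to that of their mean shares.

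The tested miRNAs of the DLK1-DIO3 region were higher in Duroc testis as a group. This imprinted region expresses its miRNA clusters from the maternal chromosome. The list had 24 members in the files, of which 11 passed the filter. The others were not tested, and the 3 Duroc libraries alone can meet that filter. Of the 11 members tested, 10 had higher means in Duroc, with a median log2 fold change of 1.79, and 9 lay above every Large white library in each of the 3 Duroc libraries with TMM scaling, as did 4 with total scaling. miR-381-3p, the most abundant, had 883 ± 197 normalised RPM in Duroc and 327 ± 50.1 in Large white (SD, n = 3 each), with a log2 fold change of 1.43 that was 0.73 with total scaling, where the libraries overlapped. miR-127 had 72.7 ± 29.8 and 26.9 ± 5.36, and miR-370 had 12.4 ± 5.64 and 2.84 ± 1.43.

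The list passed camera with an adjusted p of 3.73e-06 and fry with an adjusted p of 0.0236. With an estimated correlation the adjusted p was 0.116. No member passed the adjustment over all miRNAs, and 10 did so adjusted over the list alone, of which miR-542-3p was lower in Duroc, at 197 ± 47.3 against 299 ± 41.7 normalised RPM (SD, n = 3 each). miR-542 lies on chromosome X from 110382597 to 110382676. Without it the list held 9 members with a median log2 fold change of 1.98 and a camera adjusted p of 6.69e-09. On Sscrofa11.1, miR-127 lies on chromosome 7 at 121709636 to 121709715 within the span of RTL1, and miR-136 at 121711328 to 121711409, within the spans of RTL1 and of a long non-coding RNA. miR-493 lies at 121697837 to 121697919, outside any gene listed. miR-381 lies at 50024 to 50105 of a sequence without a chromosome. Several members rest on few reads, such as the 6 reads of miR-758 and the 3 of miR-382 summed over the Large white libraries. The median of 1.98 is the value of miR-493-3p, with 5 reads there, so its size is imprecise. The most abundant of the 9, miR-381-3p and miR-127, had a log2 fold change of 1.43 each. Against Large white, Duroc library 2 alone had a list median of 1.20, with a camera adjusted p of 0.000142 and a fry adjusted p of 0.166, for which the Large white libraries alone gave the spread. Leaving out 1 library gave camera adjusted p-values between 1.09e-06 and 0.000247.

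**Figure D2:**
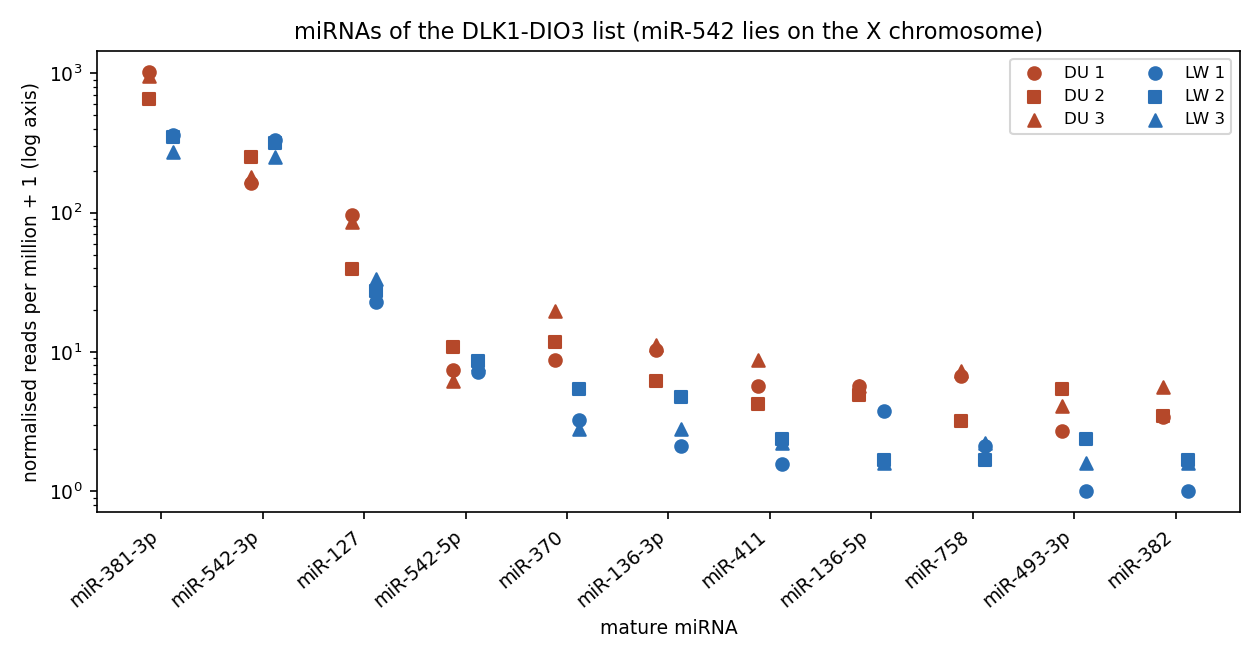
Normalised RPM plus 1 (log axis) of the 11 tested members of the DLK1-DIO3 list in each of the 6 small RNA libraries, with breed as colour and library number as symbol. For the 9 members other than miR-542 all 3 Duroc libraries lie above all 3 Large white libraries with TMM scaling, as for miR-381-3p with means of 883 and 327, whose libraries overlap with total scaling.

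The miR-17-92 cluster and its paralogues, miRNAs tied to proliferating cells, were lower in Duroc as a group. The median log2 fold change was -0.79 over 11 members, of which 10 were lower in Duroc and 6 lay below every Large white library in all Duroc libraries. miR-92a, the most abundant, had 792 ± 67.9 normalised RPM in Duroc and 875 ± 37.5 in Large white, and miR-20a-5p had 368 ± 221 and 801 ± 120 (SD, n = 3 each). miR-17 lies on chromosome 11 at 60734656 to 60734732. The list passed camera with an adjusted p of 0.0003, against an adjusted p of 0.487 with an estimated correlation and a fry adjusted p of 0.195. No member passed adjusted over the list alone. The list medians against the Large white mean were -1.04 and -0.95 in Duroc libraries 1 and 3, which stood apart, and -0.09 in Duroc library 2. The 6 members that did not overlap lay below Large white in Duroc library 2 by definition, so they are no separate evidence for that library. That library alone gave an adjusted p of 0.438, with the spread from Large white only.

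miR-34c, abundant in meiotic and later male germ cells, had 2774 and 4156 normalised RPM in Duroc libraries 1 and 3, against 15862 in Duroc library 2 and 12228 to 15959 in Large white. Its log2 fold change was -0.94 (SE 0.59), which did not pass (adjusted p = 0.430), and its family had only 2 tested members, with a median of -0.88, and was not tested as a list. Of the spermatogonia list, miR-182 had 430 ± 268 in Duroc and 1056 ± 93.1 in Large white (SD, n = 3 each), and miR-183 from the same cluster had 139 ± 80.3 and 310 ± 66.1. Not all members of that list were low in both Duroc libraries 1 and 3. With TMM scaling 5 of its 11 members had a positive log2 fold change between the breeds and 6 a negative one. Among the 5 were miR-146a-5p (0.50), miR-222 (0.39) and miR-221-3p (0.36), none of which passed. These fold changes include Duroc library 2. In Duroc libraries 1 and 3, miR-146a-5p had 709 and 226 normalised RPM against 297 to 559 in Large white. There miR-222 had 309 and 833 against 300 to 407, and miR-221-3p 322 and 506 against 258 to 337. With TMM scaling, miR-21-5p had 77358 and 55918 normalised RPM in Duroc libraries 1 and 3 against 31028 to 42150 in Large white, but its shares of reads, 3.59% and 4.43%, lay within the 3.58% to 5.73% of Large white. The precursors of miR-182 and miR-183 lie on chromosome 18 between 18982269 and 18986913. The list as a whole did not pass camera, with a median log2 fold change of -0.26 and an adjusted p of 0.105, and 6 of 11 members were lower in Duroc.

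miRNAs of smooth muscle and stroma were higher in Duroc with TMM scaling, in 19 of 21 members and with a median log2 fold change of 0.56, but their median was -0.25 with reads scaled to the library total. miR-100 had 26652 ± 12175 normalised RPM in Duroc and 15585 ± 1871 in Large white, and miR-22-3p had 3278 ± 1096 and 2266 ± 185 (SD, n = 3 each). Of the 21, only miR-22-3p had no overlap between the breeds. The log2 fold change was 0.14 for miR-145-5p, whose precursor lies beside that of miR-143, and -0.01 for miR-10b. In Duroc library 3 miR-145-5p had 1500 normalised RPM, within the 1487 to 2068 of Large white. The camera adjusted p was 0.0166, against an adjusted p of 0.898 with an estimated correlation and a fry adjusted p of 0.495. No member passed adjusted over the list alone. The list median was 1.14 in Duroc library 1, 0.46 in Duroc library 3 and -0.17 in Duroc library 2. The call was lost without Duroc library 1 (adjusted p = 0.682, median 0.08) or Large white library 1 (adjusted p = 0.110, median 0.45), and Duroc library 2 alone gave a median of -0.18. The median of all miRNAs was 0.06 with TMM and -0.56 with total scaling, so that under the latter the list lay 0.31 above it.

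The X-linked list was lower in Duroc by a small amount with TMM scaling, with a median log2 fold change of -0.25 and 13 of 18 members lower. With total scaling its median was -0.80, against -0.56 for all miRNAs. miR-450c-5p, the most abundant, had 1932 ± 602 normalised RPM in Duroc and 2273 ± 335 in Large white, and miR-450b-5p had 507 ± 176 and 965 ± 133 (SD, n = 3 each). The camera adjusted p was 0.0387, against an adjusted p of 0.487 with an estimated correlation and a fry adjusted p of 0.195. No member passed adjusted over the list alone. The call was lost without Duroc library 1 (adjusted p = 0.143, median -0.13), Duroc library 2 (0.171, median -0.35), Large white library 1 (0.105, median -0.17) or Large white library 2 (0.0820, median -0.20), with the direction kept in each, and the adjusted p with Duroc library 2 alone, where Large white alone gave the spread, was 0.269.

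The remaining lists did not pass. miRNAs of Sertoli and Leydig cells had a median log2 fold change of 0.07 (adjusted p = 0.861), and miR-202-5p, a gonadal miRNA, had 9579 ± 347 normalised RPM in Duroc and 11155 ± 816 in Large white (SD, n = 3 each). Blood cell miRNAs had a median of -0.16 (adjusted p = 0.579), with miR-451 of red cells at 4030 ± 1934 and 2686 ± 1130. The let-7 family had a median of 0.16 (adjusted p = 0.610), the striated muscle miRNAs of 0.35 (adjusted p = 0.610), and the epithelial miR-200 family of 0.45 (adjusted p = 0.861). The medians of these 3 and of the Sertoli and Leydig list were below 0 with total scaling, and above the median of all miRNAs with either scaling. let-7f-5p had 19479 ± 3346 in Duroc and 18907 ± 821 in Large white, miR-1 had 5133 ± 2175 and 5727 ± 1331, and miR-200b had 225 ± 134 and 242 ± 46.3.

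**Figure D3:**
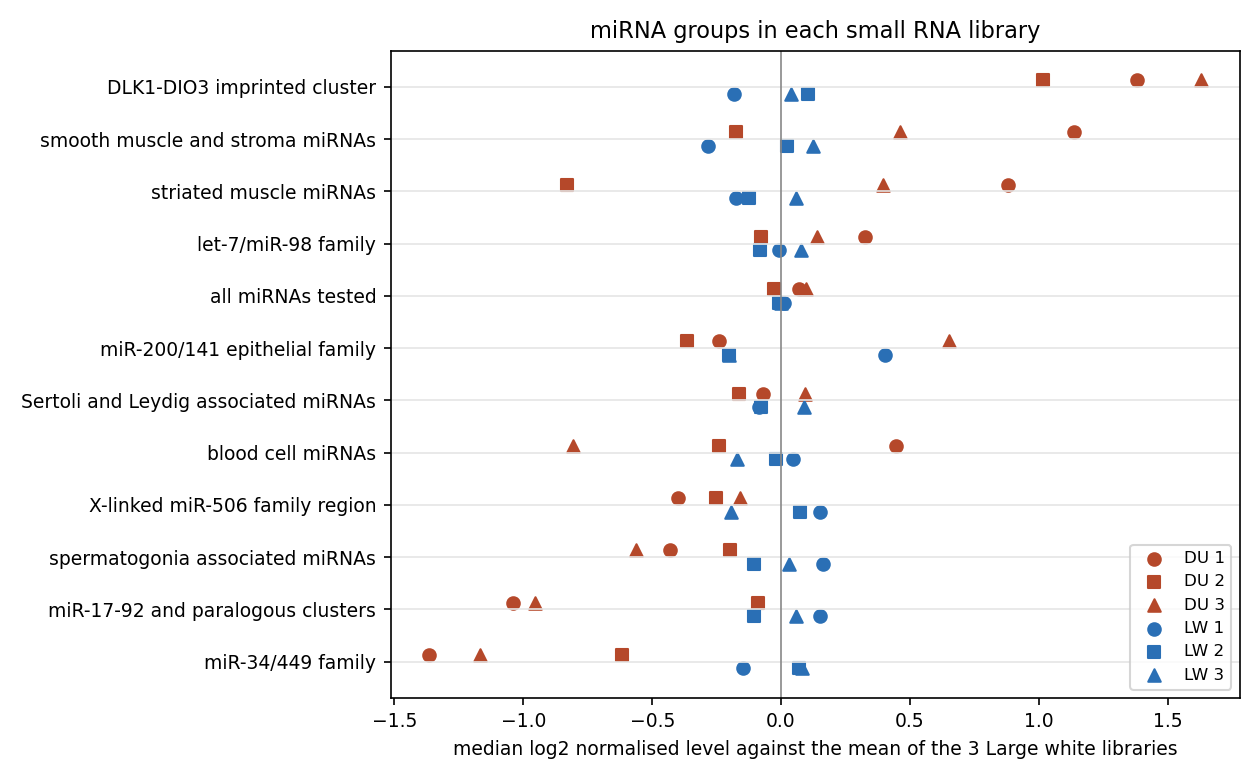
Median over each miRNA list of log2(normalised RPM + 1) against the mean of the 3 Large white libraries, for each of the 6 small RNA libraries, with breed as colour and library number as symbol. The DLK1-DIO3 medians of the 3 Duroc libraries, 1.38, 1.02 and 1.63, lie to the right of all Large white libraries, while the miR-17-92 and stroma medians of Duroc library 2, -0.09 and -0.17, lie among them.

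No single miRNA passed edgeR's test over the 421 tested, of which 300 carry a miRNA name and 121 are unnamed loci. Before adjustment 60 lay under 0.05, of which 33 were higher in Duroc and 27 in Large white, and the smallest adjusted p was 0.0974. DESeq2 called 9 higher and 5 lower in Duroc, among them miR-381-3p, miR-127, miR-370, miR-129a-5p and miR-27a, and limma called none. An unnamed locus of chromosome 3, chr3_26304, had 25.3 ± 19.1 normalised RPM in Duroc and 1.42 ± 0.24 in Large white (SD, n = 3 each; log2 fold change 4.12, SE 0.71, edgeR adjusted p = 0.0974). It had only 9 reads summed over the Large white libraries, near the floor, so the size of this fold change is imprecise. miR-1285 had 31.4 ± 2.82 in Duroc and 84.2 ± 20.1 in Large white (log2 fold change -1.42, SE 0.28, the same adjusted p). The unnamed loci chr5_30680, with 7.89 ± 3.26 and 27.0 ± 9.45, and chr3_23861, with 4.55 ± 0.82 and 13.4 ± 4.48, did not pass either (adjusted p = 0.193 each). Without Duroc library 2, edgeR called 64 miRNAs, and miR-34c then had a log2 fold change of -2.07 (adjusted p = 0.00127, the range over all settings reaching 0.795). Without Duroc library 3 it called 1, chr3_26304.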

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

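The tests with DESeq2 on transcripts, Duroc library 2 alone, every miRNA entry as deposited and the DLK1-DIO3 list without miR-542 were chosen after the data were seen; limma at a pseudocount of 1 was planned, and edgeR took its place because the files held reads. Against 9 transcripts called by edgeR, limma on log2(TPM + 1) called 20, with pseudocounts of 0.5 and 0.1 29 and 20, without its trend 20, with quantile normalisation 27, and DESeq2 428. All 9 were also called by limma with a pseudocount of 1, by DESeq2 and without Duroc library 2. Leaving out 1 library gave 0 to 8373 transcripts, 0 to 64 miRNAs and 2 to 4 lists. Against 0 miRNAs, omitting the filter gave 5, DESeq2 14 and Duroc library 2 alone, with its spread from Large white only, 1. Against 4 lists, an estimated correlation gave 0, fry 1, log2(RPM + 0.1) 2, Duroc library 2 alone 1, and fry on that library 0; the stroma list then had a median of -0.18 by both tests. The cause of these changes was not tested, except that 87 of the simulated DESeq2 calls were false. Fewer libraries leave less to estimate the spread, which does not account for the rise without Duroc library 2. Duroc libraries 1 and 3 differed from each other by more than 4-fold in 540 transcripts. From Duroc library 2 they differed in 2945 and 1189, so that leaving it out narrows the spread in Duroc. With the replicate number as a block, which pairs libraries of different breeds, the counts were 0 transcripts, 1 miRNA and 3 lists. Deviations of same-numbered RNA libraries correlated at -0.01, 0.02 and 0.02 and of small RNA libraries at -0.24, -0.13 and -0.06. These values gave no sign that the numbers pair the samples, but 3 libraries per breed are too few to exclude it. Settings not run because no gene names were at hand were gene sums, long non-coding and protein-coding classes and gene lists. Of the single transcripts, miRNAs and lists under all settings, 57, 350 and 117 values stayed on their side of the threshold, where direction was compared only if a value passed it, 19, 0 and 21 lost the threshold in the same direction, 0, 24 and 0 gained it, and 2 more list values, those of the stroma list with Duroc library 2 alone, lost it and reversed. Direction is that of the list test: with log2(RPM + 0.1) camera still placed the stroma list above the other miRNAs, while its median was -0.16. In these counts a value that passed neither in the main test nor under the setting counts as staying. That covers all 350 miRNA values and every value of the lists that did not pass. The 21 and the 2 list values that lost the threshold came from the 4 lists that passed. The 117 are therefore no sign that the list calls were stable. In the Large white small RNA libraries, depth limits miRNAs under 2.03 RPM.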

Other observations

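All tests in this part were chosen after the data had been seen. Of the miRNAs of chromosome X, 38 were tested from 29 precursors and 26 were lower in Duroc, with a median log2 fold change of -0.24. This count includes 18 miRNAs of the fixed lists. Of the 20 outside them, 13 were lower and 7 higher in Duroc, with a median of -0.11. The log2 fold change was -0.60 for miR-374a-3p, -0.51 for miR-374b-5p, -0.78 for miR-362 and -0.81 for miR-500-5p, and 0.69 for miR-105-1, 0.55 for miR-452 and 0.21 for miR-652. Several of the 20 are arms of the same precursor and are not independent. On chromosome 11 all 9 tested miRNAs were lower in Duroc, with a median of -0.71, but 6 of them are the miR-17-92 members already described. The 15 of chromosome 18, of which 3 are in the fixed lists, had a median of -0.37. The 7 of chromosome 8, from only 4 precursors, had a median of 0.69. Among the 19 chromosomes with at least 3 tested miRNAs, chromosome 8 had the highest median and chromosomes 11 and 18 the lowest, and they are named for that.

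All 12 tested unnamed loci on unplaced sequence lay on 1 scaffold. Of these, 9 were higher in Duroc, and the highest ranked had 86.1 ± 37.6 normalised RPM in Duroc and 19.9 ± 6.28 in Large white (SD, n = 3 each; log2 fold change 2.10). A hypothesis is that they belong to the DLK1-DIO3 clusters, since in the RefSeq table miR-381 and DIO3, at 504081 to 506187, lie on sequence without a chromosome, while DLK1, at 121565844 to 121577493, and MEG3 lie on chromosome 7. miR-126, which is not of this region, is listed without a chromosome too, so that this placement alone does not mark the region. The median log2 fold change of the 12 was 0.96, higher than in 99.5% of 100000 random sets of 12 unnamed loci, but the scaffold was picked for its high loci, so this restates the pattern and the hypothesis stays open. The 3 others were lower in Duroc, among them the most abundant, with 494 ± 181 and 719 ± 52.8. Most of the 9 higher loci had Large white levels near the floor, so that their direction is imprecise. An example is 1 locus with 1.69 ± 1.13 in Duroc and 1.61 ± 0.56 in Large white (log2 fold change 0.13). The table does not name the scaffold, so the match of sequences was not made.

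The higher level of the tested DLK1-DIO3 miRNAs in Duroc has a technical explanation in scaling and another in the shift of Duroc libraries 1 and 3. Over 4 scalings the median log2 fold change of the 9 members without miR-542 was between 1.49 and 1.99 and no member fell below 0.66, while the stroma list went from 0.56 to -0.25, which argues against the first, although only 4 of the 9 did not overlap with total scaling. In Duroc library 2, which does not stand apart, all 9 lay above every Large white library and their median was 1.06, against -0.27 to 0.24 in the Large white libraries, which argues against the second as the whole cause. The real split of the 6 libraries gave a median of 1.98 and the highest of the other 9 splits 1.08, but 10 splits are too few for a share under 0.05, and in 1 of the 10 the median was as large, the real one. A difference of the breeds, such as an allele at this locus or the proportion of somatic cells that express it, may remain and was not tested.

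Duroc libraries 1 and 3 had high miR-143-3p and low miR-34c, miR-182 and miR-17-92. After thinning the small RNA libraries to 1015560 reads without miR-143-3p, either of them differed from a Large white library by more than 4-fold in at least 15 of 302 miRNAs with 10 reads or more on average, against at most 7 between Large white libraries, which argues against depth and that miRNA as the whole cause. That limit of 10 reads was set only after the same test over every tested miRNA had given 33 and 29, which decided nothing. The medians of 20 classes of transcript length spread over at most 0.32 (log2), against 0.20 between Large white libraries, and the longest class lay 0.18 to 0.25 above the shortest, which argues against loss of long transcripts as the source of 4-fold differences. A lower share of germ cells stays open: the stroma median lay above that of the Sertoli and Leydig list by 1.21 in library 1 and 0.37 in library 3, against at most 0.10 in Large white, but members of the latter list went both ways, with an SD of 0.55 and 0.34, which does not decide it. More stroma or vessel in the piece sampled and a difference in maturity or health of the animals stay open too and were not tested.

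Some transcripts were read in every library of a breed, at a TPM of 1 or more, and in none of the other. There were 18 read only in Duroc and 10 only in Large white. Since the reference assembly is from a Duroc animal, sequence that differs from it may take reads from Large white and would favour the first kind. The exact two-sided binomial test gave p = 0.185, and the transcripts are few. The test could not tell this explanation from a true absence of expression at any number. More transcripts with reads in Duroc would give the same excess. Duroc libraries 1 and 3 had reads in 46316 and 44461 transcripts, against 42641 in Duroc library 2 and 43011 to 43328 in Large white. Assignment of reads to another transcript of the same gene stays open too, as no gene sums were made. The real split gave 28 such transcripts and the highest of the other splits 21, so 1 of the 10 gave as many, and 10 splits are too few for a share under 0.05.

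For the counts of calls, the 10 splits of the 6 libraries are too few for a share under 0.05. The real split called 9 transcripts and the highest other 0, so 1 of 10 splits gave as many. It called 0 miRNAs, as did all 10. It called 4 lists and the highest other 3, so 1 of 10 gave as many. Every other split, each of which mixes the breeds, called 1 to 3 lists. A list called by camera at the preset correlation is therefore not by itself a sign of a breed difference.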
